A study of Homo sapiens with 12 samples.

How the data were processed

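Total RNA of THP-1 cells was sequenced on an Illumina platform 24 h after adding LPS from B. fungorum, S. marcescens or P. myrsinacearum at 2 ng per ml, or after culture in medium alone. The authors deposited 1 table of raw counts, whole numbers of reads per Ensembl gene ID, with 1 column per library and no normalization. Trimmomatic 0.39, FastQC and STAR 2.7 are named in the submitters' processing notes, with no role or order. The counting tool, strand setting, genome build and annotation release are not given in the sources used here. Of 58676 gene IDs in the deposited table, 58676 were found in GENCODE release 29, from which gene types, symbols and coordinates were taken, and 58207 had a symbol in a newer name table. Because the strand setting is not known, values of genes that overlap on opposite strands, such as IFIT1 and LIPA, are uncertain, as are those of near-identical copies such as CCL4 and CCL4L2.

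Libraries were placed in groups by the treatment in their labels, and columns were matched to libraries by title. Replicate pairs within a group differed by more than sampling noise (chi-square over degrees of freedom from 2.23 to 9.29). This excess may be technical and does not show that the libraries came from separate cultures. Each of the 12 libraries was counted as a sample of its own. Depth was 15814823 to 19960067 counts per library. The common biological coefficient of variation was 4.98%.

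Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (15294 genes), library sizes were scaled by TMM, and a quasi-likelihood model with robust dispersion estimation was fitted to all 12 libraries with 1 coefficient per group, leaving 8 residual degrees of freedom. Each pair of groups was compared with a two-sided quasi-likelihood F test, and an F test with 2 degrees of freedom asked for any difference among the 3 LPS groups. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Confidence intervals of 95% used a t distribution with those 8 degrees of freedom and can be wider than the test implies. CPM values used TMM-scaled library sizes.

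Gene lists with at least 5 tested members were compared with other genes by camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of each comparison. Alternatives were camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and compares them with no other genes. The lists covered inflammatory cytokines, chemokines, NF-kB genes, interferon-stimulated genes, LPS recognition, other pattern receptors, feedback inhibitors, proteases, eicosanoid synthesis, neutrophil-type effectors, monocyte and macrophage markers, MHC class I and II, metallothioneins, glycolysis, oxidative phosphorylation, mitochondrially encoded genes, cholesterol synthesis, lipid efflux, cell cycle, ribosomal proteins, immediate early, heat shock, unfolded protein, hypoxia and oxidative stress genes, and markers of lymphocytes, erythroid cells and platelets, epithelium and stroma, and dendritic cells.

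The genes named in the text were taken from those a rule gave. For each comparison with medium the rule took the 8 largest increases and 8 largest decreases, and between LPS groups the 5 and 5, among genes past the test with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups, which 10% of unchanged genes show by chance for 3 against 3. Genes without a symbol, pseudogenes, uncharacterised loci, microRNA host genes and antisense genes were skipped. The rule also took up to 4 members of each list with the largest change past the test, and always TNF, IL1B, IL6, IL10, CXCL8, CCL2, CXCL10, IFIT1, NFKBIA, PTGS2, TLR4, LY96 and CD14. Genes named outside the rule are said to be chosen after their values were seen. CCL4 in the comparison of P. myrsinacearum LPS with medium is such a case.

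The groups, models, gene lists, rule for named genes and first set of alternatives were chosen before the data were examined. The alternatives were DESeq2 1.42.0, median-ratio (RLE) scaling, no low-count filter, a fit of only the 6 libraries compared, the replicate number as a block, and leaving out each replicate in turn. Removing each library's trend with exon length and GC content, and testing only protein-coding genes of at least 5 CPM, were added after the data were seen.

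The steps were tested on simulated counts drawn from the real means in medium and the real library sizes, with 50 genes changed at each fold. The changed genes were drawn only from genes above a minimum abundance in medium, so recovery of rarer genes was not measured. Far fewer genes were changed than were called in the data. For P. myrsinacearum LPS against medium (14259 genes) the test recovered 48% of genes changed 1.25-fold, 84% at 1.5-fold, 94% at 2-fold and 98% at 4-fold, and 6 unchanged genes were called. For S. marcescens against B. fungorum LPS (14287 genes) it recovered 56%, 84%, 96% and 96%, and 10 unchanged genes were called. Overlaps between comparisons that share the medium libraries were set beside 20 simulations of unchanged groups against those libraries. These groups were drawn around the means of the medium libraries, so the error shared through the controls was left out.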

Results

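The series holds RNA sequencing of THP-1 cells, a human monocytic leukaemia line widely used as a model of monocytes. Cells received lipopolysaccharide (LPS), the outer membrane glycolipid of Gram-negative bacteria that TLR4 senses together with LY96 (MD-2) and CD14, isolated from B. fungorum, S. marcescens or P. myrsinacearum at 2 ng per ml, or medium alone. RNA was taken after 24 h. Each of the 4 groups has 3 libraries, 12 in all. Total counts ranged from 15814823 to 19960067 per library, with a mean ± SD of 19223949 ± 640840 in medium, 16992830 ± 1026133 with B. fungorum LPS, 17855302 ± 1241456 with S. marcescens LPS and 17233610 ± 1614143 with P. myrsinacearum LPS. Of 58676 genes listed, 32906 had a count in at least 1 library and 15294 were abundant enough to test. In a principal component analysis of log CPM (counts scaled to library size), the first component held 49.7% of the variance and set the medium libraries (mean score -54.2 ± 3.19 SD) apart from those with B. fungorum LPS (25.8 ± 2.25) and S. marcescens LPS (25.04 ± 3.14), with P. myrsinacearum LPS between them (3.40 ± 2.87). On the second component P. myrsinacearum LPS was not intermediate, with a mean score of 25.79 ± 1.31 SD. The scores there were -6.97 ± 4.15 in medium, -11.56 ± 6.43 with B. fungorum LPS and -7.26 ± 1.89 with S. marcescens LPS. Values after ± are standard errors for log2 fold changes and standard deviations over 3 libraries for CPM. The labels do not say that libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

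With B. fungorum LPS, THP-1 cells carried far more inflammatory mRNA than in medium after 24 h. IL1B, which encodes the cytokine interleukin-1 beta, rose from 2.50 ± 0.44 to 83.0 ± 3.6 CPM (log2 fold change 5.04 ± 0.10, adjusted p = 6.0e-30). TNF rose from 4.84 ± 1.1 to 56.4 ± 5.5 CPM (3.54 ± 0.11, adjusted p = 9.8e-24), and CXCL8, the neutrophil-attracting chemokine interleukin-8, from 5.36 ± 0.57 to 90.3 ± 4.4 CPM (4.08 ± 0.08, adjusted p = 1.9e-29). The largest increases among genes of at least 5 CPM included CCL4 (7.03 ± 0.30), TNFAIP6 (5.87 ± 0.14), CCL20 (5.34 ± 0.32) and SLAMF7 (4.65 ± 0.17). The largest decreases at that abundance included the complement subunits C1QC (-2.65 ± 0.20, from 11.5 to 1.82 CPM) and C1QA (-2.07 ± 0.24), the LPS co-receptor CD14 (-1.84 ± 0.17, from 12.4 to 3.47 CPM), the scavenger receptor CD163 (-1.67 ± 0.25) and the receptor tyrosine kinase KIT (-1.61 ± 0.15). In the GENCODE annotation TNF lies on chromosome 6 from 31575567 to 31578336, IL1B on chromosome 2 from 112829751 to 112836903 and C1QC on chromosome 1 from 22643630 to 22648110. Counts are per gene, so exons and introns cannot be told apart.

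Among the lists of genes, 32 of 35 NF-kB family members and targets were higher with B. fungorum LPS than in medium and 0 lower (32 and 0 adjusted over the list alone, median 1.53, camera adjusted p = 1.9e-112), with NFKBIA, the inhibitor of NF-kB, at 1.31 ± 0.05. Of 19 chemokines 16 rose and 1 fell (16 and 1 adjusted over the list alone, median 3.30, adjusted p = 1.5e-17), among them CXCL10 (3.88 ± 0.12) and CCL2 (from 1.05 ± 0.16 to 6.82 ± 2.1 CPM, adjusted p = 2.7e-11). Of 15 inflammatory cytokines 11 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 1.2e-09). Interferon-stimulated genes rose in 43 of 54 cases and fell in 6 (43 and 7 adjusted over the list alone, median 0.93, adjusted p = 3.8e-26), with IFIT1 at 2.14 ± 0.13 and CXCL11 at 3.30 ± 0.30. The oxidative stress list was also raised (12 higher and 3 lower of 22, 12 and 4 adjusted over the list alone, adjusted p = 8.2e-09), led by HMOX1, heme oxygenase 1 (2.73 ± 0.08), and OSGIN1 (2.41 ± 0.10). Feedback inhibitors rose in 17 of 31 cases and fell in 6 (18 and 6 adjusted over the list alone, adjusted p = 2.7e-04). Monocyte and macrophage markers fell in 16 of 28 cases and rose in 6 (16 and 6 adjusted over the list alone, adjusted p = 6.7e-04), and cholesterol and fatty acid synthesis genes fell in 18 of 30 and rose in 4 (21 and 4 adjusted over the list alone, adjusted p = 1.2e-04), with the desaturase SCD at -1.20 ± 0.06.

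Calls for 9 further lists in this comparison were lost with an estimated correlation between genes, and each such p is given in the same place. Of 50 ribosomal protein genes 47 fell and 0 rose (48 and 0 adjusted over the list alone, median -0.22, adjusted p = 5.1e-09, and adjusted p = 0.20 with an estimated correlation). Of 15 heat shock genes 11 fell and 0 rose (11 and 0 adjusted over the list alone, adjusted p = 4.4e-04, and adjusted p = 0.066 with an estimated correlation), with the chaperone HSPA8 at -0.54 ± 0.04. Immediate early genes rose in 14 of 19 cases and fell in 1 (14 and 1 adjusted over the list alone, adjusted p = 7.2e-06, and adjusted p = 0.066 with an estimated correlation), with the transcription factor EGR2 at 4.46 ± 0.34. MHC class II and costimulation genes rose in 6 of 16 cases and fell in 4 (6 and 4 adjusted over the list alone, adjusted p = 0.0021, and adjusted p = 0.098 with an estimated correlation), among the rises the dendritic cell maturation marker CD83 (3.15 ± 0.08) and the costimulatory receptor CD40 (2.24 ± 0.11). Neutrophil-type and calgranulin effectors fell in 9 of 19 cases and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.0049, and adjusted p = 0.16 with an estimated correlation), with S100A8 at -1.14 ± 0.08 and lysozyme (LYZ) at -0.79 ± 0.04. Nuclear oxidative phosphorylation genes fell in 24 of 34 cases and rose in 1 (24 and 1 adjusted over the list alone, adjusted p = 6.4e-04, and adjusted p = 0.20 with an estimated correlation). Lipid efflux and LXR target genes fell in 7 of 13 cases and rose in 0 (9 and 0 adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.20 with an estimated correlation), and hypoxia genes fell in 8 of 17 and rose in 2 (8 and 2 adjusted over the list alone, adjusted p = 0.025, and adjusted p = 0.077 with an estimated correlation). Mitochondrially encoded genes rose in 8 of 13 cases and fell in 0 (9 and 0 adjusted over the list alone, adjusted p = 0.0036, and adjusted p = 0.43 with an estimated correlation), and the mitochondrial share of counts was 3.57%, 4.66% and 4.87% in the B. fungorum LPS libraries against 3.11% ± 0.304 in medium.

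The remaining lists did not pass camera with B. fungorum LPS. These were LPS recognition and TLR4 signalling (11 higher and 4 lower of 26, 11 and 4 adjusted over the list alone, adjusted p = 0.21), other pattern receptors and inflammasome (6 and 4 of 21, 6 and 5 adjusted over the list alone, 0.41), and proteases and their inhibitors (7 and 7 of 23, 7 and 7 adjusted over the list alone, 0.41), where the median was -0.04 and the mean 0.16. Eicosanoid synthesis had 3 higher and 6 lower of 12 (3 and 6 adjusted over the list alone, adjusted p = 0.22) and MHC class I presentation 6 and 6 of 18 (6 and 6 adjusted over the list alone, 0.83), with a positive median and a test direction of lower. Metallothioneins had 0 higher and 1 lower of 6 (0 and 1 adjusted over the list alone, adjusted p = 0.63), glycolysis 4 and 12 of 22 (4 and 12 adjusted over the list alone, 0.27) and the cell cycle 7 and 23 of 40 (7 and 23 adjusted over the list alone, 0.058), although the proliferation marker MKI67 was higher (1.92 ± 0.12). The unfolded protein response had 9 higher and 3 lower of 20 (10 and 4 adjusted over the list alone, adjusted p = 0.078), and epithelial and stromal markers 0 higher and 1 lower of 7 (0 and 1 adjusted over the list alone, 0.33). Lymphocyte, erythroid and platelet, and dendritic cell markers had fewer than 5 tested members (4, 3 and 4) and were not tested as lists. The receptor gene TLR4 fell slightly (-0.40 ± 0.09, adjusted p = 2.5e-04), whereas LY96 gave 0.05 ± 0.48 (adjusted p = 0.95). IL6 and IL10 were not tested, with 11 and 9 counts over the 12 libraries.

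**Figure D1:**
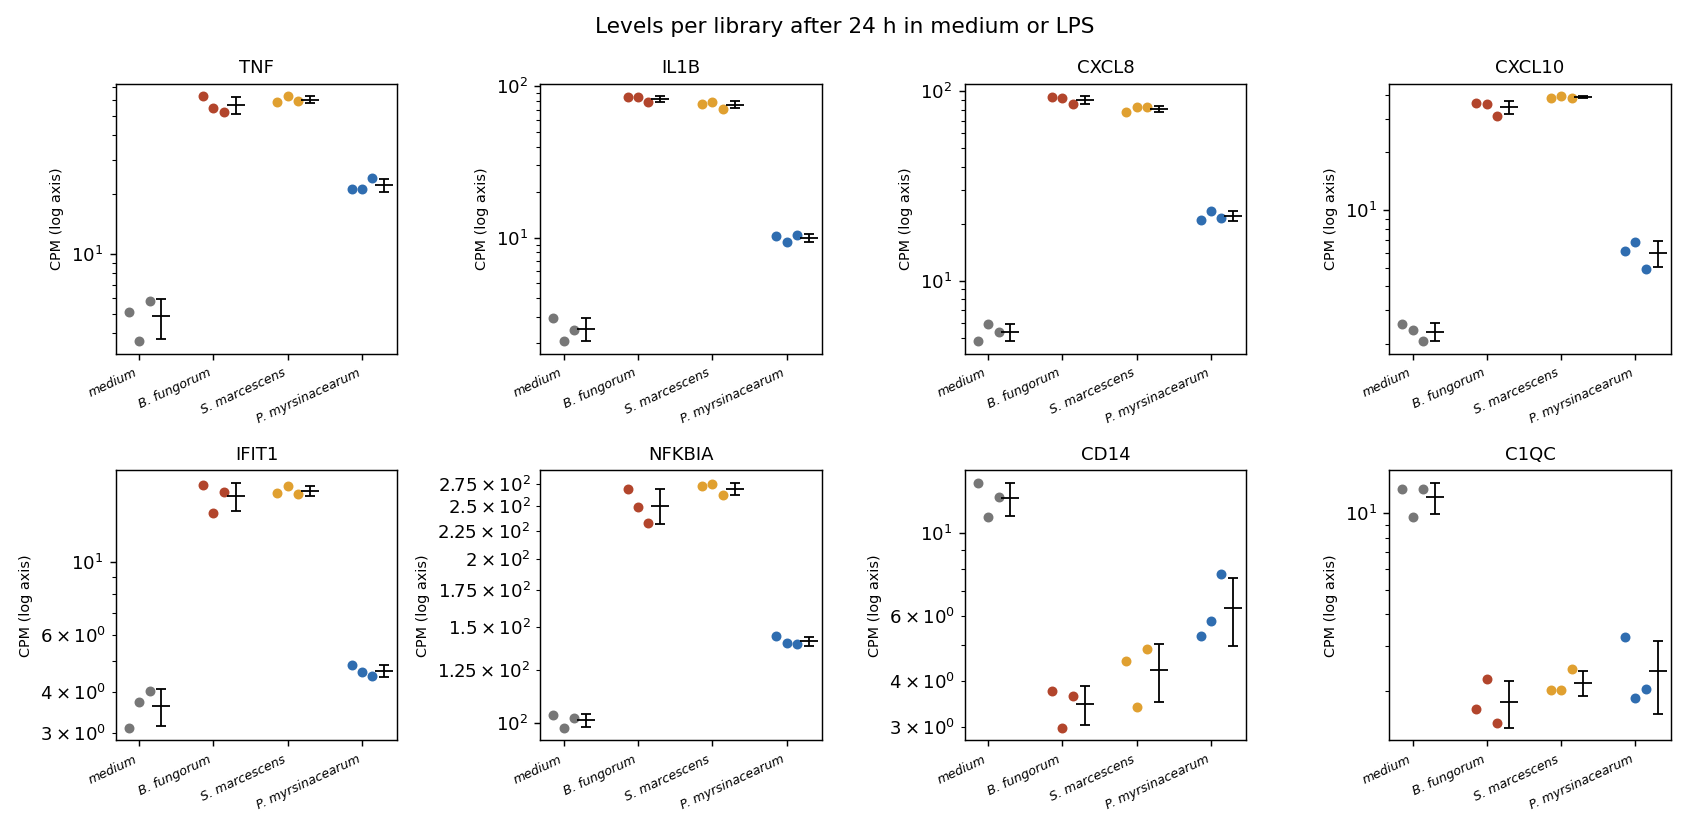
Expression of 8 genes in medium and with each LPS, in CPM on a log axis. Points are the 3 libraries of a group, the bar is their mean and the error bar their SD; TNF stood at 4.84 CPM in medium and at 56.4 CPM with B. fungorum, 60.3 CPM with S. marcescens and 22.3 CPM with P. myrsinacearum LPS.

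In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7575 of 15294 genes differed between B. fungorum LPS and medium, 3847 higher and 3728 lower. Changes of at least 2-fold were 1384 higher and 168 lower. Among 9971 protein-coding genes of at least 5 CPM, a set chosen after the data were seen, 5542 differed, 314 of them at least 2-fold higher and 29 at least 2-fold lower. The nuclear RNAs MALAT1 and NEAT1, chosen after their values were seen, stood at 24.0 ± 4.2 and 10.9 ± 1.1 CPM in medium and at 98.6 ± 10 and 56.9 ± 5.9 CPM with B. fungorum LPS. CCL4 and its near-identical copy CCL4L2 (7.08 ± 0.45) share reads, and IFIT1 overlaps LIPA on the other strand, so their values are uncertain where the counting is not given as stranded.

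With S. marcescens LPS the same inflammatory genes were raised to similar levels over medium. IL1B reached 75.6 ± 4.1 CPM (log2 fold change 4.91 ± 0.10, adjusted p = 1.5e-29), TNF 60.3 ± 2.3 CPM (3.64 ± 0.11, adjusted p = 4.3e-24), CXCL8 80.9 ± 3.0 CPM (3.92 ± 0.08, adjusted p = 8.0e-29) and CXCL10 38.8 ± 0.52 CPM (4.05 ± 0.12, adjusted p = 1.8e-24). CCL4 (6.43 ± 0.32) and TNFAIP6 (5.83 ± 0.14) had the largest increases after CCL4L2 among genes of at least 5 CPM. C1QC (-2.41 ± 0.19), C1QA (-2.34 ± 0.25), the kinase gene MAP2K6 (-1.57 ± 0.15), CD14 (-1.54 ± 0.16) and the gelatinase gene MMP9 (-1.53 ± 0.15) had the largest decreases at that abundance. TLR4 fell (-0.45 ± 0.09) and LY96 gave -0.28 ± 0.49 (adjusted p = 0.66).

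Of 35 NF-kB genes 32 rose and 0 fell with S. marcescens LPS (33 and 0 adjusted over the list alone, median 1.55, camera adjusted p = 1.0e-114). Of 54 interferon-stimulated genes 44 rose and 1 fell (44 and 1 adjusted over the list alone, median 0.99, adjusted p = 4.5e-34), with IFIT1 at 2.19 ± 0.13. Chemokines rose in 16 of 19 cases and fell in 1 (16 and 2 adjusted over the list alone, adjusted p = 2.1e-17), and cytokines rose in 11 of 15 and fell in 2 (11 and 2 adjusted over the list alone, adjusted p = 4.0e-10). Heat shock genes fell in 13 of 15 cases and rose in 0 (13 and 0 adjusted over the list alone, adjusted p = 1.0e-04), cholesterol and fatty acid synthesis genes fell in 19 of 30 and rose in 3 (20 and 3 adjusted over the list alone, adjusted p = 1.5e-05), and monocyte and macrophage markers fell in 17 of 28 and rose in 5 (17 and 6 adjusted over the list alone, adjusted p = 9.7e-04). Ribosomal protein genes fell in 49 of 50 cases and rose in 0 (49 and 0 adjusted over the list alone, adjusted p = 1.9e-13, and adjusted p = 0.10 with an estimated correlation). Immediate early genes rose in 13 of 19 cases and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 4.3e-07), and oxidative stress genes rose in 10 of 22 and fell in 3 (10 and 3 adjusted over the list alone, adjusted p = 4.3e-06), with HMOX1 at 2.11 ± 0.08. Mitochondrially encoded genes did not pass (1 higher and 1 lower of 13, 0 and 0 adjusted over the list alone, adjusted p = 0.62), and the mitochondrial share of counts was 3.47% ± 0.154.

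In edgeR's test, 7502 genes differed between S. marcescens LPS and medium, 3855 higher and 3647 lower, with 1406 at least 2-fold higher and 127 at least 2-fold lower. Among the abundant protein-coding genes 5470 differed, 314 of them at least 2-fold higher. MALAT1 stood at 102 ± 25 CPM and NEAT1 at 62.9 ± 12 CPM. With an estimated correlation 10 of the 16 lists past camera were called.

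With P. myrsinacearum LPS the inflammatory genes rose less. TNF reached 22.3 ± 1.7 CPM (log2 fold change over medium 2.20 ± 0.12, adjusted p = 4.3e-16), CXCL8 21.9 ± 1.3 CPM (2.04 ± 0.09, adjusted p = 7.2e-18), IL1B 9.96 ± 0.59 CPM (1.98 ± 0.13, adjusted p = 2.9e-14) and CXCL10 5.96 ± 0.93 CPM (1.36 ± 0.16, adjusted p = 1.4e-08). NFKBIA rose by 0.48 ± 0.05 and CCL2 by 0.99 ± 0.28, while IFIT1 gave 0.36 ± 0.16 (adjusted p = 0.062) and CCL4 1.51 ± 0.66 (adjusted p = 0.068). C1QC fell by 2.27 ± 0.19, C1QA by 2.06 ± 0.24, MMP9 by 1.45 ± 0.14, CD14 by 0.99 ± 0.15 and TLR4 by 0.39 ± 0.09 on the log2 scale. The largest increases among genes of at least 5 CPM were of CAMKV (3.27 ± 0.23), GOLGA8A (2.66 ± 0.19), MYO15B (2.60 ± 0.26), CCDC27 (2.48 ± 0.30), MSH5 (2.43 ± 0.34) and the dynein gene DNAH1 (2.42 ± 0.16), which had also risen with B. fungorum LPS (2.93 ± 0.24, 2.31 ± 0.20, 2.43 ± 0.27, 2.03 ± 0.31, 2.24 ± 0.35 and 2.51 ± 0.16). GOLGA8A has close copies, and CCDC27 and MSH5 overlap TP73-AS1 and SAPCD1, so these values are uncertain.

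Of 35 NF-kB genes 28 rose and 0 fell with P. myrsinacearum LPS (28 and 0 adjusted over the list alone, median 0.69, camera adjusted p = 1.2e-32). Interferon-stimulated genes did not pass as a list, with 17 of 54 higher and 10 lower (19 and 10 adjusted over the list alone, median 0.11, adjusted p = 0.21). Heat shock genes fell in 12 of 15 cases and rose in 0 (13 and 0 adjusted over the list alone, adjusted p = 1.8e-08), with HSPA8 at -0.58 ± 0.04. Cholesterol and fatty acid synthesis genes fell in 19 of 30 cases and rose in 1 (19 and 1 adjusted over the list alone, adjusted p = 5.2e-08), with SCD at -1.04 ± 0.05, and monocyte and macrophage markers fell in 15 of 28 and rose in 4 (16 and 4 adjusted over the list alone, adjusted p = 8.8e-04). Chemokines rose in 9 of 19 cases and fell in 1 (10 and 2 adjusted over the list alone, adjusted p = 0.0047, and adjusted p = 0.15 with an estimated correlation), and cytokines rose in 4 of 15 and fell in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.0045, and adjusted p = 0.15 with an estimated correlation). Ribosomal protein genes fell in 48 of 50 cases and rose in 0 (49 and 0 adjusted over the list alone, adjusted p = 1.0e-26, and adjusted p = 0.058 with an estimated correlation). Neutrophil-type effectors fell in 10 of 19 cases and rose in 2 (11 and 2 adjusted over the list alone, adjusted p = 1.0e-04, and adjusted p = 0.090 with an estimated correlation), with S100A8 at -0.98 ± 0.08. Glycolysis genes fell in 13 of 22 cases and rose in 2 (14 and 2 adjusted over the list alone, adjusted p = 0.010, and adjusted p = 0.15 with an estimated correlation). Immediate early genes rose in 12 of 19 cases and fell in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.0012, and adjusted p = 0.15 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 20 of 34 cases and rose in 1 (22 and 2 adjusted over the list alone, adjusted p = 3.5e-05, and adjusted p = 0.15 with an estimated correlation).

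**Figure D2:**
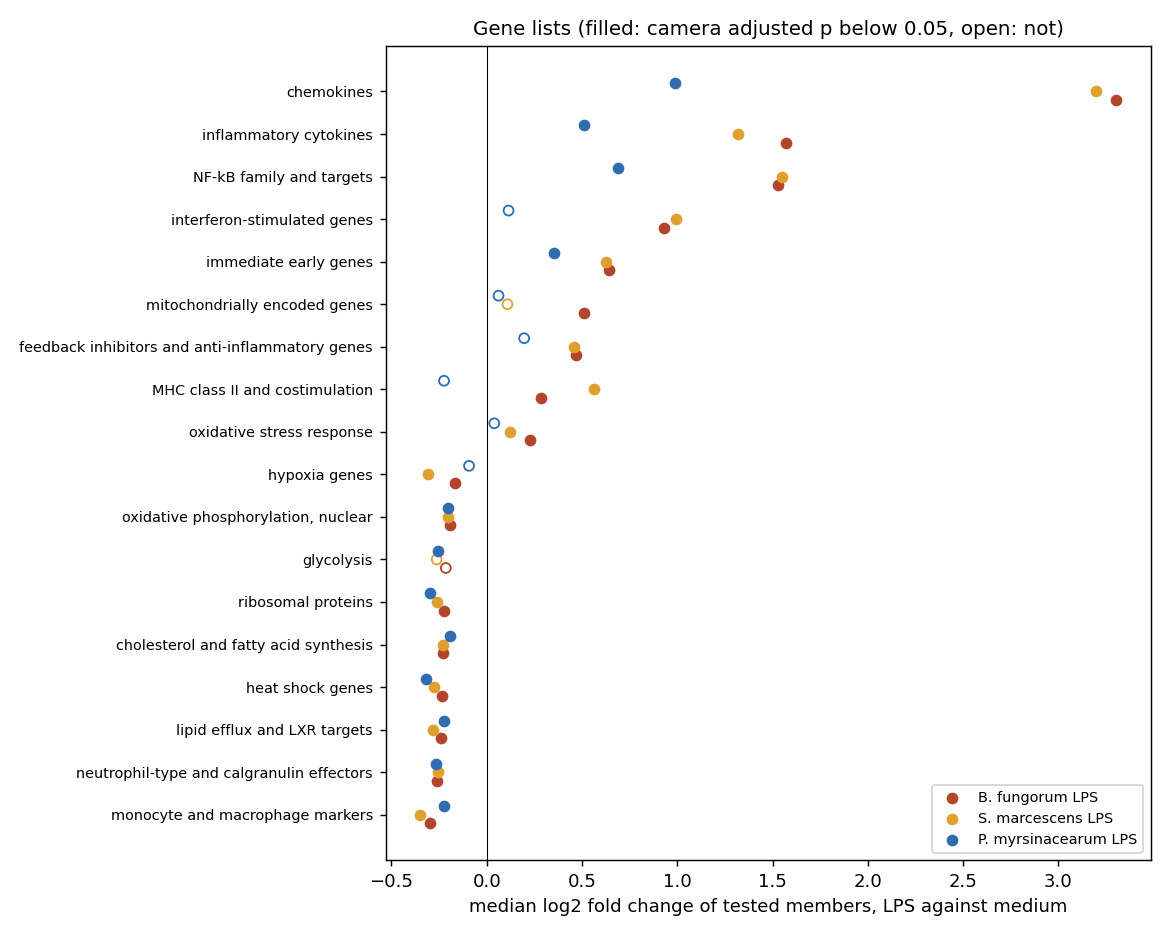
Median log2 fold change of 18 gene lists against medium for each LPS, for lists past camera in at least 1 of these comparisons. Filled points have an adjusted p below 0.05; the NF-kB median was 1.53 with B. fungorum, 1.55 with S. marcescens and 0.69 with P. myrsinacearum LPS.

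In edgeR's test, 6088 genes differed between P. myrsinacearum LPS and medium, 3060 higher and 3028 lower, with 1015 at least 2-fold higher and 58 at least 2-fold lower. Among the abundant protein-coding genes 4413 differed, 157 of them at least 2-fold higher and 5 at least 2-fold lower. MALAT1 stood at 109 ± 6.7 CPM and NEAT1 at 52.7 ± 7.8 CPM. PTGS2 (0.72 ± 0.26, adjusted p = 0.026) lost its call without medium replicate 1 (adjusted p = 0.076, range over its alternatives 0.019 to 0.11), P. myrsinacearum replicate 1 (0.061) or replicate 2 (0.11). LY96 (-1.91 ± 0.60, adjusted p = 0.011, 109 counts over 12 libraries) lost its call without medium replicate 1 (adjusted p = 0.11, range 0.010 to 0.11) or P. myrsinacearum replicate 2 (0.068). IFIT1 was called without medium replicate 3 (0.46, adjusted p = 0.042, range 0.028 to 0.25).

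**Figure D3:**
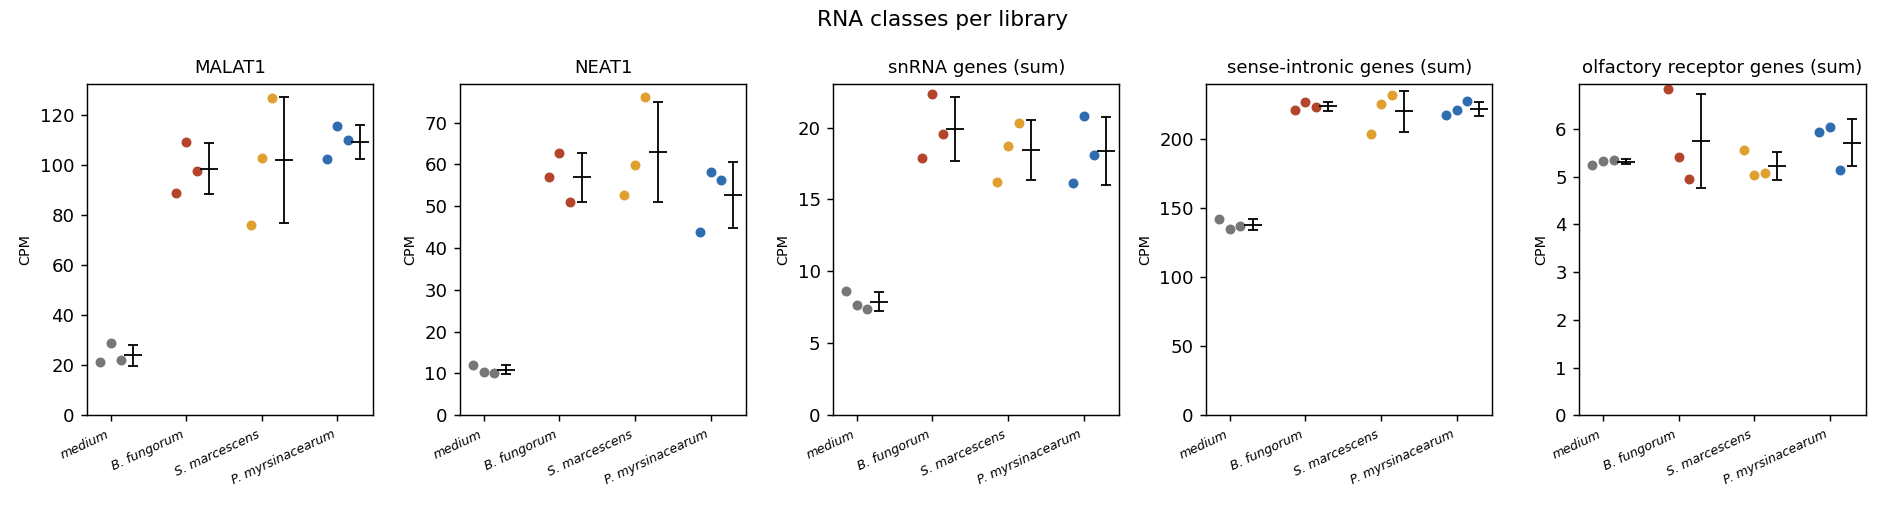
Summed expression of MALAT1, NEAT1, small nuclear RNA, sense-intronic transcripts and olfactory receptor genes in CPM, on linear axes from 0. Points are the 3 libraries of a group, with their mean and SD; small nuclear RNA stood at 7.91 CPM in medium and at 19.9 CPM with B. fungorum, 18.4 CPM with S. marcescens and 18.4 CPM with P. myrsinacearum LPS.

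Genes that changed with 1 LPS tended to change with the others. B. fungorum and S. marcescens LPS shared 3340 higher genes against 969.7 for independent lists, 3063 lower genes against 889.0, and 0 genes called in opposite directions by edgeR. B. fungorum and P. myrsinacearum LPS shared 2560 higher genes against 769.7 and 2425 lower genes against 738.1, and S. marcescens and P. myrsinacearum LPS shared 2646 against 771.3 and 2525 against 722.1. Of genes higher or lower with B. fungorum LPS, 25 and 10 were called in the opposite direction with P. myrsinacearum LPS, and of those higher or lower with S. marcescens LPS, 18 and 5. Across genes, which are not independent replicates, fold changes over medium correlated with r = 0.942, 0.838 and 0.849 for these pairs. The covariances were 0.512, 0.385 and 0.385. In 20 simulations of unchanged groups against the same medium libraries the medians were r = 0.0286, a covariance of 0.0012 and 0 shared calls. The simulated groups were drawn around the means of those medium libraries, which leaves out the error shared through the controls. The simulations therefore cannot show how much of the overlap the shared controls give. The 3 medium libraries are too few to split, so part of the excess may come from the shared controls. Part may also come from the higher nuclear and intronic RNA in all LPS libraries. As described below, that rise cannot be told apart from different recovery of nuclear RNA, so the overlap need not be a common response.

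Comparing S. marcescens with B. fungorum LPS directly gave few differences. HMOX1 was lower with S. marcescens LPS (65.4 ± 2.3 against 100.3 ± 12 CPM; log2 fold change -0.62 ± 0.07, adjusted p = 5.5e-06), as was the fatty acid activating enzyme ACSL1 (265 ± 6.4 against 339 ± 10 CPM; -0.35 ± 0.04, adjusted p = 2.6e-05). The kinase gene SGK1 (-0.43 ± 0.08) and the lipid droplet coat protein PLIN2 (-0.31 ± 0.05) were also lower, and the lipid antigen presenting molecule CD1D was higher (0.49 ± 0.09, adjusted p = 0.023). TNF differed by 0.09 ± 0.08 (95% confidence interval -0.08 to 0.27, adjusted p = 0.82), IL1B by -0.13 ± 0.06 (-0.28 to 0.01, adjusted p = 0.66) and IFIT1 by 0.05 ± 0.11 (-0.20 to 0.31, adjusted p = 0.95). The IL1B interval is wider than edgeR's test implies, since its unadjusted p was 0.038. CXCL8 differed by -0.16 ± 0.06 (-0.30 to -0.02, adjusted p = 0.56) and NFKBIA by 0.11 ± 0.04 (0.0032 to 0.21, adjusted p = 0.65). Neither passed after adjustment.

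In edgeR's test 8 of 15294 genes differed between S. marcescens and B. fungorum LPS, 1 higher and 7 lower, with 1134 at an unadjusted p below 0.05. CD1D, SGK1 and PLIN2 lost their calls without B. fungorum replicate 2 (adjusted p = 0.093, 0.14 and 0.060) or without S. marcescens replicate 3 (0.092, 0.14 and 0.077). Over their alternatives the adjusted p ranged from 0.0013 to 0.17 for CD1D, 4.3e-04 to 0.15 for SGK1 and 2.3e-05 to 0.077 for PLIN2. CD1D was also lost without S. marcescens replicate 1 (0.15) or replicate 2 (0.17), and SGK1 without S. marcescens replicate 1 (0.15). The number of genes called was 2 without B. fungorum replicate 2, 4 without S. marcescens replicate 1, 2 without S. marcescens replicate 3 and 486 without B. fungorum replicate 1. Mitochondrially encoded genes were lower as a list (median -0.34, 0 of 13 called and 0 adjusted over the list alone, camera adjusted p = 8.9e-25, and adjusted p = 0.092 with an estimated correlation), beside the mitochondrial shares of 3.47% and 4.37%. The share in B. fungorum replicate 1 was 3.57%, within the range of the S. marcescens libraries (3.36% to 3.65%). Interferon-stimulated genes were higher (median 0.10, 0 of 54 called and 0 adjusted over the list alone, adjusted p = 1.8e-07, and adjusted p = 0.092 with an estimated correlation). The oxidative stress list was lower (1 of 22 called and 6 adjusted over the list alone, adjusted p = 4.0e-07, and adjusted p = 0.092 with an estimated correlation), as were ribosomal protein genes (0 of 50 called and 1 adjusted over the list alone, adjusted p = 1.8e-07, and adjusted p = 0.62 with an estimated correlation).

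P. myrsinacearum LPS gave less inflammatory mRNA than B. fungorum LPS in the direct test. CCL4 was lower by a log2 fold change of -5.52 ± 0.25 (0.305 ± 0.23 against 14.9 ± 2.5 CPM, adjusted p = 1.5e-18), TNFAIP6 by -3.48 ± 0.11, IL1B by -3.06 ± 0.08 (adjusted p = 1.5e-25), CXCL10 by -2.52 ± 0.10, CXCL8 by -2.04 ± 0.07, CD83 by -1.88 ± 0.07, IFIT1 by -1.77 ± 0.13 (adjusted p = 3.7e-13) and TNF by -1.34 ± 0.09 (adjusted p = 2.2e-14). Higher with P. myrsinacearum LPS were the telomerase gene TERT (1.24 ± 0.19, 8.77 ± 0.74 against 3.66 ± 1.2 CPM), LGALS12 (1.14 ± 0.21), the haematopoietic transcription factor NFE2 (10.3 ± 0.51 against 5.12 ± 0.34 CPM, adjusted p = 7.1e-07) and CD1D (0.99 ± 0.09). In medium TERT, NFE2 and CD1D stood at 7.78 ± 1.5, 11.4 ± 0.52 and 27.9 ± 2.7 CPM. CD14, which fell less, was also higher (0.85 ± 0.18, adjusted p = 6.9e-04). LY96, at a low level, was lower (-1.95 ± 0.60, 0.173 ± 0.069 against 0.677 ± 0.26 CPM, adjusted p = 0.023). TLR4 gave 0.01 ± 0.09 (adjusted p = 0.95).

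Of 35 NF-kB genes 30 were lower with P. myrsinacearum than with B. fungorum LPS and 0 higher (30 and 0 adjusted over the list alone, median -0.96, camera adjusted p = 3.4e-143). Interferon-stimulated genes were lower in 42 of 54 cases and higher in 0 (47 and 0 adjusted over the list alone, median -0.77, adjusted p = 8.2e-66), chemokines in 14 of 19 and 0 (15 and 0 adjusted over the list alone, adjusted p = 4.9e-33) and cytokines in 9 of 15 and 1 (9 and 1 adjusted over the list alone, adjusted p = 5.5e-14). The oxidative stress list was lower in 12 of 22 cases and higher in 0 (13 and 0 adjusted over the list alone, adjusted p = 1.6e-14), with HMOX1 at -1.36 ± 0.07. MHC class II and costimulation genes were lower in 6 of 16 cases and higher in 0 (6 and 0 adjusted over the list alone, adjusted p = 2.3e-07). Mitochondrially encoded genes were lower as a list (0 of 13 called and 12 adjusted over the list alone, adjusted p = 2.8e-06, and adjusted p = 0.31 with an estimated correlation), beside mitochondrial shares of 3.39% and 4.37%. The share in B. fungorum replicate 1 was 3.57%, within the range of the P. myrsinacearum libraries (2.96% to 3.76%). In edgeR's test 2333 genes differed, 901 higher and 1432 lower, with 34 at least 2-fold higher and 236 at least 2-fold lower. Among the abundant protein-coding genes 2168 differed, 2 at least 2-fold higher and 101 at least 2-fold lower.

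**Figure D4:**
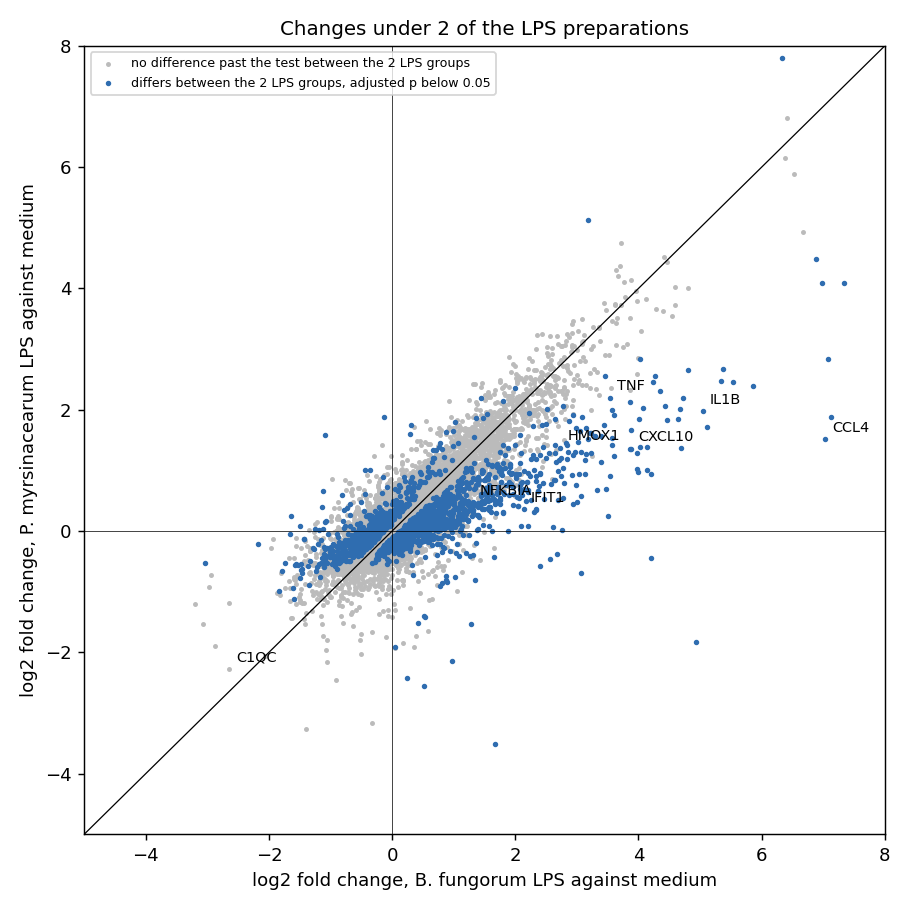
Log2 fold change over medium of 15294 genes with B. fungorum LPS (horizontal axis) and P. myrsinacearum LPS (vertical axis). Blue points are the 2333 genes that differed between these LPS groups, 1 gene lies outside the axes, and both axes share the 3 medium libraries.

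Against S. marcescens LPS, P. myrsinacearum LPS gave a like set of differences. CCL4 was lower (-4.91 ± 0.27), as were TNFAIP6 (-3.44 ± 0.11), IL1B (-2.93 ± 0.08, adjusted p = 6.8e-25), SLAMF7 (-2.81 ± 0.13), CXCL10 (-2.69 ± 0.10), IFIT1 (-1.83 ± 0.13) and TNF (-1.43 ± 0.08, adjusted p = 3.6e-15). LGALS12 (0.99 ± 0.21), NFE2 (0.99 ± 0.13), TERT (0.87 ± 0.18) and the inflammasome receptor NAIP (0.76 ± 0.15) were higher. NF-kB genes were lower in 30 of 35 cases and higher in 0 (30 and 0 adjusted over the list alone, median -0.93, camera adjusted p = 4.7e-165), and interferon-stimulated genes in 47 of 54 and 0 (48 and 0 adjusted over the list alone, median -0.82, adjusted p = 7.6e-101). Immediate early genes were lower in 8 of 19 cases and higher in 1 (8 and 1 adjusted over the list alone, adjusted p = 8.4e-07, and adjusted p = 0.050 with an estimated correlation). LPS recognition genes were lower in 7 of 26 cases and higher in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.043, and adjusted p = 0.077 with an estimated correlation). In edgeR's test 1671 genes differed, 584 higher and 1087 lower, with 14 at least 2-fold higher and 211 at least 2-fold lower. Among the abundant protein-coding genes 1564 differed, and the 90 that differed at least 2-fold were lower. CD14 was higher (0.55 ± 0.17, adjusted p = 0.031) but lost this call without S. marcescens replicate 2 (adjusted p = 0.20) or P. myrsinacearum replicate 3 (adjusted p = 0.24), with a range over its alternatives of 0.019 to 0.24.

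A test for any difference among the 3 LPS groups called 2082 genes. Without B. fungorum replicate 1 it called 3183 genes and without P. myrsinacearum replicate 3 it called 1382.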

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

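The search for genes with opposite directions and both scaling tests of interferon-stimulated genes were chosen after the results were seen.

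Against medium, 21 genes passed edgeR's test in opposite directions with P. myrsinacearum LPS and with both other LPS, 20 of them protein coding at 5 CPM or more. They were also required to pass the direct tests of P. myrsinacearum LPS against each other LPS. Their differences between P. myrsinacearum and B. fungorum LPS are given for size and are no separate test. The genes were picked for opposite changes and for passing those direct tests. Those lower with P. myrsinacearum LPS and higher with the others included CYBB, the catalytic subunit of the phagocyte NADPH oxidase (-0.33 ± 0.06 over medium with P. myrsinacearum and 0.29 ± 0.06 with B. fungorum LPS; direct difference -0.61), the pore-forming protein MPEG1 (-0.66), the oxygen-sensitive transcription factor HIF1A (-0.46), complement C3 (-0.27) and the interferon-induced MX2 (-0.48). The direct differences were -0.90 for the carboxypeptidase M gene CPM, -1.11 for HS3ST3B1, -0.76 for MYO10, -0.75 for RFTN1, -1.06 for ADAMDEC1, -0.88 for SAMSN1, -0.50 for PRKD3, -0.40 for SEC22B, -0.42 for LGR4, -0.41 for HSD11B1 and -0.27 for UGP2. Higher with P. myrsinacearum LPS and lower with the others were SLC12A9 (0.33), CSPG4 (0.43), OSBPL5 (0.47) and GRAMD4 (0.58). Most changes over medium were small, and adjusted p with P. myrsinacearum LPS ranged from 1.0e-06 for ADAMDEC1 to 0.039 for SEC22B. Apart from ADAMDEC1 and CYBB, these genes were not refitted under other settings.

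Interferon-stimulated genes stood out because their list passed against medium with B. fungorum and S. marcescens LPS but not with P. myrsinacearum LPS, and differed in the direct tests. Across list members, the change with P. myrsinacearum LPS was 0.396 of the mean change with the other LPS for NF-kB genes and 0.320 for interferon-stimulated genes. A reduction in the same proportion as NF-kB genes left a median residual of -0.26 log2 (49 of 54 members negative, which are not independent). The NF-kB ratio was taken without error. The 27 members with the strongest responses to the other LPS gave -0.25 (23 negative). They were picked by the same mean change that the residual subtracts, which pushes it down. Whether smaller responses were merely harder to detect therefore stays open. As a hypothesis, P. myrsinacearum LPS may engage the interferon arm less than the NF-kB arm of the response. A response that is not proportional to dose stays open, since 1 dose was used, and the medium libraries enter both lists' changes.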

How the results depend on the processing

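Removing length and GC trends and testing only abundant protein-coding genes were chosen after the data were seen. No gene count, list count, list or named gene changed direction past the test under the settings run. The 7 counts of changed genes stayed within 1.5 times under DESeq2, RLE scaling, fits of the 6 libraries compared (not run for the test among 3 groups), trend removal and abundant protein-coding genes. With no low-count filter S. marcescens against B. fungorum LPS gave 33 genes instead of 8. Camera with an estimated correlation called 8 lists for B. fungorum, 10 for S. marcescens and 4 for P. myrsinacearum LPS against medium (17, 16 and 12 with the preset correlation) and 0 for S. marcescens against B. fungorum LPS (4). Fry called 21 lists for P. myrsinacearum LPS against medium, 0 for S. marcescens against B. fungorum LPS, and 18 and 14 for P. myrsinacearum against B. fungorum and S. marcescens LPS (10 and 9 with camera). Fry tests another null hypothesis; for the other settings the cause was not tested.

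Leaving out 1 replicate at a time, S. marcescens against B. fungorum LPS ranged from 2 genes (without B. fungorum replicate 2 or S. marcescens replicate 3) to 486 (without B. fungorum replicate 1) and from 4 to 8 lists (8 without B. fungorum replicate 1). The test among the 3 LPS groups ranged from 1382 genes (without P. myrsinacearum replicate 3) to 3183 (without B. fungorum replicate 1). Counts against medium ranged from 6665 to 7416, 6601 to 6911 and 5015 to 5513. The other counts and list counts stayed within 1.5 times. With length and GC trends removed S. marcescens against B. fungorum LPS without B. fungorum replicate 1 gave 375 genes, and for the other left-out replicates the cause was not tested. Leaving out P. myrsinacearum replicates 1, 2 and 3 ended 31, 33 and 30 calls among 296 named gene results, called or not, and other replicates 10 to 19 among 214 to 334. DESeq2 ended 28 calls among 520 such results, no filter 15 among 534, trend removal 12 among 534 and RLE scaling 6 among 534.

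Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated with r from -0.0486 to 0.0326, and 3 of 12 libraries correlated best with their own number. With a replicate block the counts were 7548, 7433 and 6021 against medium, 9 for S. marcescens against B. fungorum LPS, 2312 and 1615 for P. myrsinacearum against these, and 2055 among the 3 groups. At this depth genes of a few counts, such as IL6 and IL10, could not be tested.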

Other observations

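The trend removals and the splits of the libraries were set out before their results were seen. The other tests of nuclear RNA, the swap test and the choice of single genes below came after the results were seen.

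Nuclear and intronic RNA was more abundant with each LPS than in medium, to about the same level. Small nucleolar RNA stood at 9.90 ± 0.19 CPM in medium and at 22.2 ± 2.2 CPM with B. fungorum, 20.5 ± 2.2 CPM with S. marcescens and 20.9 ± 1.5 CPM with P. myrsinacearum LPS, and sense-intronic transcripts in the same order at 138 ± 3.9, 223 ± 3.1, 220 ± 15 and 222 ± 5.0 CPM. Of 772 genes at least 2-fold higher with all 3 LPS, 677 did not pass the test among the LPS groups, and 86.4% of those lay below 5 CPM.

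Genomic DNA in the LPS libraries was taken to give the whole rise of sense-intronic transcripts, spread evenly over exon length. It would then have raised 386 olfactory receptor genes by 91.5 to 95.5 CPM. The observed rise was at most 0.426 CPM (standard error 0.569), a ratio of at most 0.00446. Removing exon length and GC trends left the median of 223 sense-intronic and unclassified (TEC) genes with P. myrsinacearum LPS at 0.80, which argues against such a trend as the whole cause. A response graded with the inflammatory output would have made these genes lower with P. myrsinacearum than with B. fungorum LPS, and the median difference was -0.0108. Classes rose by folds that differed between LPS groups by at most 1.19 times, as different recovery of nuclear RNA between medium and LPS libraries would give. The classes did not share 1 fold. With B. fungorum LPS it was 1.62 for sense-intronic, 2.24 for small nucleolar and 2.52 for small nuclear RNA, 4.10 for MALAT1 and 5.25 for NEAT1. Different recovery and a response of the cells reached at each of these LPS cannot be told apart, because medium and LPS libraries differ in both. A biological response was not tested on its own.

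In the 6 libraries with B. fungorum and S. marcescens LPS, B. fungorum replicate 1 with S. marcescens replicates 1 and 3, against the rest, gave 366 genes where the real split gave 8, which points to a structure of the samples. The 141 genes higher in those 3 libraries had a median exon length of 2.96 kb and the 225 lower genes 11.2 kb. With length and GC trends removed the split called 103 genes, so such a trend may account for part of it. A swap of B. fungorum replicate 1 and S. marcescens replicate 2 stays open. The 10 genes with the smallest p between the 2 groups were taken from a fit without those libraries. Of these, 3 (ACSL1, HMOX1 and SOD2) placed both on the side of their own label. S. marcescens replicate 2 was on its own side in 7 and B. fungorum replicate 1 in 3. That fit sets S. marcescens replicates 1 and 3 against B. fungorum replicates 2 and 3, which the split above also parts. Genes of that structure could place B. fungorum replicate 1 on the other side without a swap, so these counts cannot decide. CD34 had 6 counts in B. fungorum replicate 1 and 55 in S. marcescens replicate 2, each on the side of its own label. It was not among the genes called between these groups. Because it was chosen after its counts were seen, it cannot decide on a swap.

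For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split was 1 of 10 as large for each LPS against medium (7575, 7502 and 6088 genes, highest other 0 each) and for P. myrsinacearum against B. fungorum (2333) and S. marcescens LPS (1671), with 0 as the highest other in edgeR, and 2 of 10 for S. marcescens against B. fungorum LPS (8, highest other 366). Among the 3 LPS groups 3 of 100 drawn splits, the real one included, called as many genes as the real 2082. That share is under 0.05, which makes chance an unlikely source of the count but does not exclude it. Another split called 3044, which again points to a structure of the samples.

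In P. myrsinacearum replicate 3, KRT14, KRT6B and KRT16 had 64, 60 and 40 counts, against at most 2 in any other library. KRT4 had 49 counts in B. fungorum replicate 1 and AFP 48 in medium replicate 1, each with 0 in the other libraries. HBB had 19 counts in B. fungorum replicate 3 and 8 in S. marcescens replicate 3. CD34 had 64, 55 and 86 counts with S. marcescens LPS, 6, 3 and 18 with B. fungorum LPS, 0, 1 and 0 with P. myrsinacearum LPS and 37, 7 and 9 in medium.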
